A study of Mus musculus with 15 samples.

How the data were processed

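CUT&RUN was done with an anti-NRL antibody on 250000 dissociated retinal cells per experiment, per the labels' protocols, with cleavage by protein A-MNase for 30 min and 10 pg of heterologous spike-in DNA. Libraries were made with a ThruPLEX kit and sequenced as paired ends. The submitters' processing notes name Trimmomatic 0.38, Bowtie2 2.3.5.1, SAMtools 1.9, Picard 2.20.8, MACS2 2.2.5 and bedtools 2.29.0 and the builds GRCm38.p6 (mouse) and ASM584v2 (Escherichia coli), without the role or order of each. The annotation tool, the replicates behind each peak list and the use made of the spike-in are not given in the sources used here.

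Age was the only factor, taken from the labels. They list 15 libraries; the series text speaks of quadruplicates, while P2 has 3. The quantitation table has columns for 8 libraries, replicates 3 and 4 at P2, P4 and P28 and replicates 1 and 4 at P10; the other 7 labelled libraries were not analysed here. The plan was written for 15 libraries and left the test open to the unit, so each comparison rests on 2 libraries against 2.

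The table of 8996 peaks gives RPKM, as the values show; the deposited header does not name the unit. Each column is a set of whole reads divided by a width and by 1 scale per library, and whole reads were recovered for 100% of values within 0.001 of a whole number. The width used was not always that of the peak. In the first column each value was divided by its own peak's width, and in each further column by the width of a peak 39 rows earlier than in the column before, as if a vector of 9035 widths had been recycled over 8996 rows. In the second column 57.7% of peaks were divided by a width more than 1.5 times too large or too small. RPKM was therefore rebuilt from the recovered reads with each peak's own width and the library scale behind the deposited values, and the values as deposited were kept as an alternative chosen after seeing the data. Rank correlation with the authors' peak signal rose on rebuilding, for example from 0.514 to 0.628 in P4 replicate 3 and from 0.680 to 0.794 in P4 replicate 4. The scales, from 5.26e+06 to 8.01e+06, are not whole reads, and how the authors set them is not given in the sources used here. Reads in peaks, in the order of the columns, were 78255, 49430, 85740, 150878, 195736, 227692, 98186 and 92360.

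The deposited lists, 1 per age, hold for each peak a signal and a score made by the authors' calling and reproducibility step; the score ran from 541 to 1000 and the p and q columns of these lists held no values. The signal and score are the authors' own and were used only to rank peaks within a list. Peak place, distance to the nearest TSS and gene symbol are the authors' annotation. Gene identifiers were matched to a RefSeq gene table of GRCm38.p6 (8995 of 8996 peaks) for gene type. Peaks within 1 kb of a TSS are called promoter peaks.

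Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with trend and robust empirical Bayes, all 8 libraries in 1 fit with age as factor (4 residual degrees of freedom), no filter, and Benjamini-Hochberg adjustment over all peaks; a call is an adjusted p under 0.05. Fold changes on this scale understate the change of weak peaks. For a peak with 1 to 3 reads at an age the ratio of scaled reads is given with an exact 95% interval, and for 0 reads a bound from 3 reads. The same scale, threshold and design served each comparison of consecutive ages and P28 against P2, and an F test served any age. Gene lists were tested with camera (preset correlation 0.01) on 1 peak per protein-coding gene, the strongest within 50 kb of its TSS, for 5978 genes. The 16 lists were rod phototransduction and outer segment, photoreceptor transcription factors, cone genes, bipolar markers, progenitor and neurogenic genes, the cell cycle, amacrine, horizontal and ganglion cell markers, Müller glia, bZIP factors, the photoreceptor cilium, the photoreceptor synapse, glycolysis and energy metabolism, ribosomal proteins, chromatin modifiers, pigment epithelium, and microglia with vessels; 13 had at least 3 genes with a peak and were tested. Overlaps count 1 bp or more. Shares have Wilson 95% intervals. Position and list presence were tested with Fisher's exact test, and the tests of presence in lists and of promoter share among called peaks were chosen after seeing the data. Peaks and genes are not replicates in these tests. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

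Named peaks followed a rule. It takes, among called peaks with mean signal at or above the median, with no overlap between the libraries of the 2 ages (33.3% by chance for 2 against 2, in either direction) and a protein-coding TSS within 50 kb, the 8 highest and 8 lowest changes for P28 against P2 and the 4 highest and 4 lowest for each step, 1 per gene. It adds up to 4 members of each list with the lowest adjusted p in P28 against P2, and 15 loci named in advance. Other list members that passed are named by symbol alone, after their values were seen. Results for some genes that the rule covers are not reported here.

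The procedure was tested on simulated data for P28 against P2, with 67, 67 and 66 of 8996 peaks changed 2-, 4- and 8-fold. It recovered 0% of peaks changed 2-fold, 38.8% of those changed 4-fold and 71.2% of those changed 8-fold, and 4 of its 77 calls were false. Each simulated library had the same expected number of reads in peaks, whereas the real ones held 49430 to 227692. These figures therefore may not hold for the real libraries. The reading of the width offset was tested on simulated columns as well, and gave the right offset in 8 of 8.

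Alternatives were median centring of each library, scaling to reads inside peaks, limma without trend, leaving out the weakest 1 in 4 peaks, pseudocounts of 0.1 and 4, only the 2 ages compared, the replicate number as a block, leaving out each library, and stricter thresholds; for lists of genes, an estimated correlation, the mean over all peaks of a gene and 10 kb from the TSS; for lists of peaks, the stricter 50% of each list, 50% reciprocal overlap, equal length and a 3 kb window. Values as deposited and limma-voom on recovered reads were added after seeing the data. Motif searches were planned and not run, since no genome sequence was used here.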

Results

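The chromatin sites held by NRL, the Maf-family basic leucine zipper (bZIP) transcription factor that sets rod photoreceptor identity, were measured in whole retinas of C57BL/6J mice at postnatal days 2, 4, 10 and 28 (P2, P4, P10 and P28). The assay was CUT&RUN, in which an antibody tethers a nuclease to its target in intact cells so that DNA next to the protein is cut out and sequenced. The title of the series asks about NRL occupancy over development and about c-Jun in early rod differentiation. The labels list 15 libraries, 3 at P2 and 4 at each other age. The quantitation table analysed here has 8 of them, 2 per age, and 8996 peaks. Reads inside these peaks ranged from 49430 in P2 replicate 4 to 227692 in P10 replicate 4, with medians of 4 and 15 reads per peak. At the median peak width, 3 reads correspond to 1.17 to 1.77 RPKM (reads scaled to peak length and library) across the libraries. The share of each library's scale that lay inside peaks was 0.940 and 0.986% at P2, 1.09 and 2.15% at P4, 2.84 and 3.08% at P10, and 1.51 and 1.52% at P28. Between the replicates of an age, log2 values across peaks correlated with Pearson r of 0.60 at P2, 0.74 at P4, 0.89 at P10 and 0.71 at P28. The P2 replicates correlated less with each other than each did with either P4 library (0.61 to 0.64). Peaks are not independent replicates. Each replicate pair differed by more than sampling noise (chi-square per degree of freedom 1.13 to 1.41), so no pair was merged. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. Intervals and floors given for reads cover counting error only. Coordinates are those of GRCm38.p6, counted from 1.

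The first comparison asked where NRL peaks were called at each age. The deposited lists grew from 1221 peaks at P2 to 3161 at P4 and 7520 at P10, and held 3482 at P28. Of 35 genes of rod phototransduction and the outer segment, 7 had a peak within 50 kb at P2 (Gnb1, Pdc, Prph2, Rom1, Rp1, Sag and Unc119), 16 at P4, 30 at P10 and 25 at P28. These are 20.0, 45.7, 85.7 and 71.4% of the list, against 4.45, 11.1, 23.4 and 13.4% of all protein-coding genes in the same peak lists. The gene of rod transducin, Gnat1, and that of a rod phosphodiesterase subunit, Pde6b, first appeared in the P4 list. Lists of different length are not equally deep, and each is the product of the authors' calling on that age.

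Most P2 peaks overlapped the longer lists of P4 and P10, and fewer did at equal list length. Of the P2 peaks, 975 (79.9%) overlapped a P4 peak and 1023 (83.8%) a P10 peak by at least 1 bp, and 751 (61.5%) overlapped a P28 peak. With the 1221 strongest peaks of each list these shares were 57.9, 42.3 and 41.4%. Of the P4 peaks, 2548 (80.6%) overlapped the P10 list. Of the P28 peaks, 2631 (75.6%) overlapped the P10 list, whereas 2642 P10 peaks (35.1%) overlapped the P28 list. Peaks found in no other list numbered 105 at P2, 473 at P4, 3767 at P10 and 783 at P28.

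Promoters took a larger share of the P28 list than of the others. Peaks within 1 kb of a transcription start site (TSS) made up 62.0% of the P2 list (Wilson 95% interval 59.2 to 64.7), 62.0% of the P4 list (60.3 to 63.7), 57.5% of the P10 list (56.4 to 58.6) and 74.4% of the P28 list (73.0 to 75.9). Introns held 24.5% of P10 peaks and 13.2% of P28 peaks. The P28 share exceeded the P10 share by 17.0 points (Fisher's exact test, two-sided, adjusted p = 9.2e-67). With the 1221 strongest peaks of each list the shares were 62.0, 54.3, 46.3 and 69.3% in order of age, and the difference of P28 from P10 was 23.0 points (adjusted p = 5.6e-30). Each age has 1 list, so these p-values cover counting of peaks only and measure no spread between samples. The lists are also not independent, since 75.6% of P28 peaks overlapped the P10 list. Among peaks found in no other list, 71.3% of the P28 peaks and 45.6% of the P10 peaks lay within 1 kb of a TSS.

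**Figure D1:**
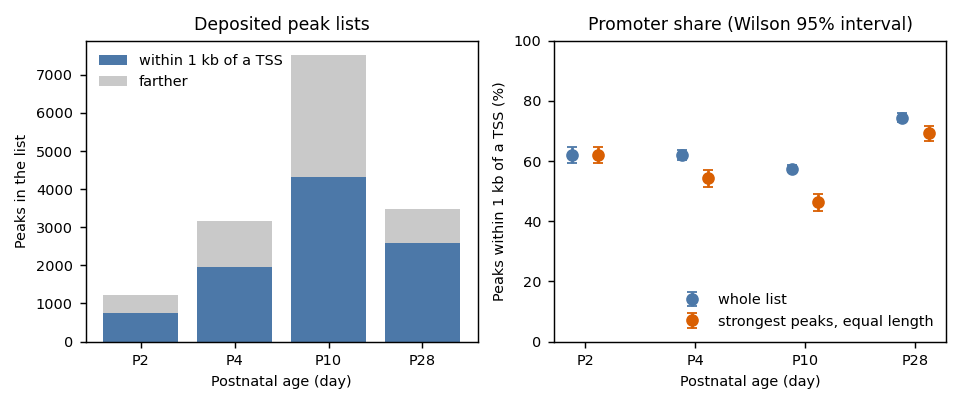
Left, number of peaks in the deposited list of each age, split at 1 kb from a transcription start site. Right, percent of peaks within 1 kb, with Wilson 95% intervals, for whole lists and for the 1221 strongest peaks of each list; the P28 list has the highest share in both forms, 74.4 and 69.3%.

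Genes of rods, of other photoreceptor functions and of housekeeping functions had NRL peaks more often than protein-coding genes at large; the lists were not tested against each other. In the combined table, 30 of the 35 rod genes had a peak within 50 kb, against 27.3% of 21896 protein-coding genes (Fisher's exact test, two-sided, odds ratio 16.1, adjusted p = 1.3e-11). This presence test was chosen after the counts were seen. The cilium list had 21 of 28 genes with a peak, the photoreceptor transcription factors 15 of 21, the synapse list 14 of 21, bZIP factors 18 of 28, glycolysis and energy metabolism 18 of 28, ribosomal proteins 20 of 32, the cell cycle 20 of 28 and chromatin modifiers 18 of 26. All of these passed adjusted p under 0.05. Their odds ratios were 8.01 for the cilium, 6.67 for the transcription factors and for the cell cycle, 6.00 for chromatin, 5.33 for the synapse, 4.80 for bZIP factors and for glycolysis, and 4.45 for ribosomal proteins. The strongest peak was a promoter peak in 19 of 20 ribosomal, 19 of 20 cell cycle and 18 of 21 cilium genes. It was in 13 of 18 chromatin, 13 of 18 bZIP and 12 of 18 glycolysis genes. The counts were 16 of 30 for rod genes, 7 of 14 for the synapse and 5 of 15 for transcription factors. Expression was not measured here, so in lists of mostly promoter peaks NRL preference cannot be told apart from open promoters of active genes. Cone genes had 7 of 18 (adjusted p = 0.36), bipolar cell markers 4 of 18, progenitor and neurogenic genes 8 of 24, and amacrine, horizontal and ganglion cell markers 3 of 20. None of 13 Müller glia markers and none of 17 microglia and vessel markers had a peak (adjusted p = 0.038 and 0.0093), and of 11 pigment epithelium markers Mitf alone did.

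The step from P2 to P4 asks about binding in the first postnatal days, when the last rods are born. No single peak passed the test. The 15 measured photoreceptor transcription factors had a median log2 difference of 0.92 and the 30 rod genes one of 0.76, against 0.47 for all 5978 genes with a peak. Both lists passed camera with its preset correlation (rod genes, adjusted p = 0.015; transcription factors, adjusted p = 0.015), and neither did with a correlation estimated from the data (adjusted p = 0.98 with an estimated correlation for each) or with the mean over all peaks of a gene (0.11 and 0.19). With the preset correlation, the rod and transcription factor lists had adjusted p = 0.84 and 0.13 without P2 replicate 3 and 0.27 and 0.40 without P4 replicate 4; the transcription factor list had 0.054 without P2 replicate 4. At the Nr2e3 exon peak, next to the gene of the orphan receptor that represses cone genes, mean RPKM was 4.06 ± 0.28 (SD, n = 2) at P2 and 14.4 ± 8.3 at P4. The Crx peak downstream of the photoreceptor homeobox gene had 9.68 ± 0.20 and 24.6 ± 14.8.

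Adjusted over the list alone, 5 rod genes rose, as did 1 gene each of the transcription factor, cone, synapse and bZIP lists. Cone genes had a median of 1.05 (adjusted p = 0.13), glycolysis 0.84 (0.15), the synapse 0.83 (0.18), the cilium 0.71 (0.62), bZIP factors 0.42 (0.94) and the cell cycle 0.57 (0.94). The bipolar, progenitor, amacrine with ganglion cell, ribosomal and chromatin lists had an adjusted p of 0.94 each. Limma called 0 of 8996 peaks at an adjusted p under 0.05, with a smallest adjusted p of 0.056. At an unadjusted p under 0.05 it found 1295 higher and 70 lower peaks, and limma-voom on the recovered reads called 8. The median peak was 0.48 higher at P4 on the log2 scale, and 886 peaks passed the unadjusted level after each library was centred on its median. Without P4 replicate 3 the count became 836, without P2 replicate 3 it was 199, without P2 replicate 4 it was 34, and without P28 replicate 3 or 4 it was 114 or 121.

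Between P4 and P10, when outer segments begin to form, NRL signal rose at 20 of 30 measured rod genes (9 with each library centred on its median), and at 7 of 14 photoreceptor synapse genes and 4 of 18 glycolysis genes (0 and 1 after centring). At the Gnat1 promoter (chromosome 9, 107679577 to 107680076) the mean went from 8.01 ± 5.23 to 60.5 ± 17.4 RPKM (SD, n = 2), a log2 change of 2.87 ± 0.58 (SE, limma, adjusted p = 0.0026). The steepest rises among well-covered peaks were in an intron of Ccdc126 (log2 4.21 ± 0.58), at −5503 bp from the TSS of Eno1, which encodes the glycolytic enzyme enolase (4.13 ± 0.56, from 2.46 to 55.7 RPKM), upstream of the chaperone gene Hsp90aa1 (4.03 ± 0.58) and in an intron assigned to Hsdl1 (3.96 ± 0.58). The largest falls were at Slc6a17, a transporter of synaptic vesicles (−3.37 ± 0.54, from 29.0 to 1.9 RPKM), Zfp41 (−3.01 ± 0.59), Vash1, which encodes the angiogenesis inhibitor vasohibin (−2.38 ± 0.52), and an intron of the SoxD factor gene Sox6, where 33 reads at P4 faced 3 at P10 (10.6-fold lower, 95% counting interval 3.33 to 54.1). The Vash1 peak lay between genes, −25745 bp from the TSS.

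Of 30 measured rod genes, 20 rose and none fell, with a median log2 change of 1.75 against 0.68 for all genes. Among them were Gnat1, the rod phosphodiesterase genes Pde6a, Pde6b and Pde6g, the channel genes Cnga1 and Cngb1, the disc-rim gene Prph2, Pdc (phosducin), Rcvrn (recoverin), Tulp1 and Aipl1. Camera gave an adjusted p of 1.6e-11 for the list (adjusted p = 0.78 with an estimated correlation), and 26 rose when adjusted over the list alone. Of 14 synapse genes, 7 rose, including the active zone gene Pclo, the ribbon gene Ctbp2, Cplx4 (a complexin), Elfn1 and Syp (synaptophysin); the list median was 1.53 (adjusted p = 0.0022, and adjusted p = 0.78 with an estimated correlation), and 10 rose adjusted over the list alone. Among photoreceptor transcription factors Esrrb, Samd11 and Mef2d rose (3 of 15, and 7 adjusted over the list alone). Camera gave this list adjusted p = 0.11, with 0.045 after centring and 0.94 with an estimated correlation. Gpi1, Ldha, Eno1 and the lactate transporter gene Slc16a1 rose among 18 glycolysis genes (adjusted p = 0.099; 7 adjusted over the list alone), and Arl3, Bbs7, Ift172 and Bbs9 among 21 cilium genes (adjusted p = 0.50; 4 adjusted over the list alone). Of the other lists, cone genes had 2 that rose (Gnat2 and Clca3a1), ribosomal proteins 2 (Rps27a and Rpl14), chromatin modifiers 2 (Dnmt3a and Crebbp), bZIP factors 1 (Fosb) and the cell cycle 1 (E2f3), with none among bipolar, progenitor or amacrine, horizontal and ganglion cell genes. These last 8 lists had camera adjusted p values of 0.36 to 0.85; adjusted over the list alone, 2 cone, 2 bipolar, 2 chromatin and 1 cell cycle gene rose, as did 2 amacrine, horizontal and ganglion cell genes while 1 fell.

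Limma called 1541 peaks, 1405 higher and 136 lower at P10 (91.2% higher); with a pseudocount of 0.1 in place of 1 it called 8. The median peak was 0.73 higher, and with each library centred on its median 259 peaks were higher and 293 lower (46.9% higher), of which 395 were also called, in the same direction, on the deposited scales. After centring 9 rod genes, 1 transcription factor, 1 cilium gene, 1 cell cycle gene and Eno1 alone of the glycolysis genes rose, and no synapse, cone, bZIP, ribosomal or chromatin gene did; Nefl, of the amacrine, horizontal and ganglion cell list, fell (adjusted p = 0.017). The count was 215 without P4 replicate 3, 221 without P10 replicate 1, 388 without P10 replicate 4 and 3040 without P4 replicate 4. Of the 8 peaks named for this step, 5 passed in each fit that left out 1 library; Zfp41 and Vash1 did not without P10 replicate 1 (adjusted p = 0.10 and 0.062), nor Sox6 without P10 replicate 4 (0.075).

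Between P10 and P28, when rods mature, most called peaks fell and a small set rose. The Gnat1 promoter had 60.5 ± 17.4 RPKM at P10 and 70.1 ± 12 at P28 (log2 0.23 ± 0.58, limma adjusted p = 0.80). The Nr2e3 exon peak (chromosome 9, 59946881 to 59947028) fell from 39.4 ± 1.5 to 7.59 ± 3.34 RPKM (−2.29 ± 0.56, adjusted p = 0.0061). The largest falls were at Fbf1, a gene of ciliary transition fibres, with 105 reads at P10 and 2 at P28 (45.9-fold lower, 95% counting interval 12.4 to 384), at Fignl2 (53.8-fold, 14.6 to 449), at Agrn, which encodes the matrix proteoglycan agrin (−4.08 ± 0.68), and in an intron of Cdhr1, the outer segment cadherin, with 35 reads and 0 (at least 10.2-fold lower, from a floor of 3 reads over the P28 libraries). Peaks that rose were at the promoters of Inpp5e, a ciliary phosphoinositide phosphatase (1.62 ± 0.51, from 3.39 to 12.4 RPKM), Tomm22, of the mitochondrial import complex (1.56 ± 0.53), and Tpm3, a tropomyosin (1.48 ± 0.48), and in an intron near Tgfb2 (1.58 ± 0.57, adjusted p = 0.0497). The named peaks of Inpp5e, Tomm22, Tpm3 and Tgfb2 were in the P28 list alone. Those of Fbf1, Fignl2 and Cdhr1 were in the P10 list alone.

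No list passed camera over this step. Each list gene was read at its strongest peak only. Nr2e3 had 3 peaks and Casz1 had 6, and the others are not given here. Among photoreceptor transcription factors Samd7, Samd11, Casz1 and Nr2e3 fell (4 of 15; adjusted p = 0.38; 4 adjusted over the list alone). Among synapse genes Pclo, Ctbp2, Nrxn3, Elfn1 and Syp fell (5 of 14, median −1.34 against −0.58 for all genes; adjusted p = 0.088, or 0.038 without P28 replicate 4; 7 adjusted over the list alone). Cone genes had 3 of 7 that fell, Gnb3, Gulo and Clca3a1 (median −1.27; adjusted p = 0.088; 6 adjusted over the list alone). Notch1 and Id3 were among the progenitor genes that fell (8 measured; adjusted p = 0.48; 3 adjusted over the list alone). Unc119 and Fscn2 were the 2 rod genes that fell (adjusted p = 0.48; 0 adjusted over the list alone), and Bbs7, Mak and Rpgrip1 were among the 4 cilium genes that did (adjusted p = 0.72; 4 adjusted over the list alone). Bach1, Crem and Atf1 fell among bZIP factors, Slc16a1 and Ldhb among glycolysis genes, Rps19 and Rpl10a among ribosomal genes, E2f3 and Cdkn1c in the cell cycle, and Nyx, Slc6a9 and Chd7 in the bipolar, amacrine and chromatin lists, with adjusted p values for these lists of 0.38 to 0.88. Adjusted over the list alone, 1 gene fell in each of the bZIP, cell cycle, bipolar and amacrine lists. After centring, 4 transcription factors, 3 synapse genes, 2 progenitor genes and 2 cilium genes fell, as did 1 gene in each of the cone, bipolar, cell cycle, amacrine, bZIP and ribosomal lists, and no rod, glycolysis or chromatin gene fell. Then 1 gene rose in each of the progenitor, amacrine, bZIP, synapse and chromatin lists.

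Limma called 1974 peaks, 116 higher and 1858 lower at P28 (5.88% higher). The median peak was lower, at −0.69, and after centring 385 were higher and 770 lower (33.3% higher), with 886 calls shared in direction with the deposited scales. The count was 507 without P10 replicate 1, 675 without P10 replicate 4, and 1154 without either P28 replicate. Of the 8 peaks named for this step, the 4 that fell passed in each fit that left out 1 library and the 4 that rose did not: adjusted p was 0.25 for Inpp5e, 0.48 for Tgfb2 and 0.16 for Tpm3 without P10 replicate 1, and 0.49 for Tomm22 without P10 replicate 4.

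**Figure D2:**
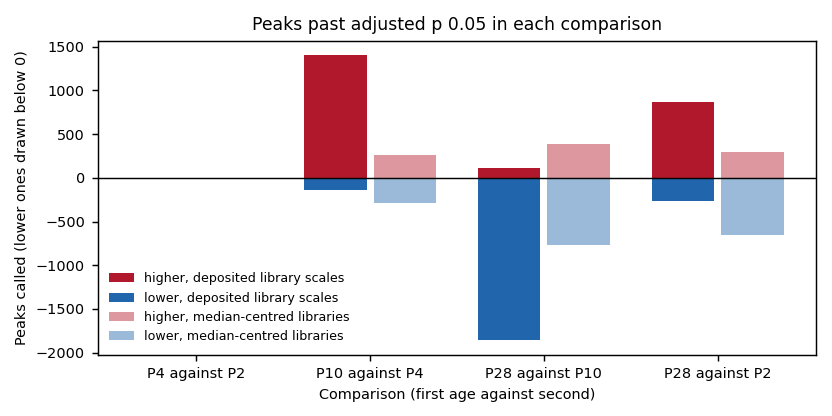
Peaks past an adjusted p of 0.05 (limma) in each comparison, with higher peaks drawn above 0 and lower ones below, on the deposited library scales and after centring each library on its median. P4 against P2 has no bar; P10 against P4 has 1405 higher and 136 lower peaks on the deposited scales and 259 and 293 after centring.

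P28 against P2 spans the whole course and asks which sites gained or lost NRL signal from newborn to mature retina. Rod genes rose: of 30 measured, 17 passed and none fell. At the Gnat1 promoter NRL signal went from 1.77 ± 1.42 to 70.1 ± 12 RPKM (SD, n = 2; log2 4.78 ± 0.58, limma adjusted p = 5.5e-05). Against this, Sox6 and a set of peaks that lay mostly away from promoters lost signal.

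The other rod peaks followed the same direction. The Pde6b promoter (chromosome 5, 108388192 to 108388546) rose from 1.96 ± 0.26 to 28.3 ± 3.0 RPKM (3.31 ± 0.54, adjusted p = 0.00041). A peak in the 3' UTR of Rcvrn, the calcium sensor of phototransduction, had 1 read at P2 and 44 at P28 (46.2-fold higher, 95% counting interval 7.87 to 1866). Prph2 rose in its intron (chromosome 17, 46912112 to 46912749) from 3.37 ± 0.30 to 21.1 ± 1.8 RPKM (2.33 ± 0.53, adjusted p = 0.0059, or 0.059 without P28 replicate 3). The others that rose were Rp1, Gnb1, Cnga1, Reep6, Unc119, Grk1, Fscn2, Pde6a, Guca1a, Guca1b, Rdh12 and Rgs9bp. The list median was 1.84 against 0.62 for all genes, camera gave an adjusted p of 4.4e-11 (adjusted p = 0.83 with an estimated correlation), and 26 rose adjusted over the list alone. With libraries centred, 12 passed. The Cngb1 promoter stood at 2.06 ± 0.59 and 8.63 ± 1.13 RPKM (1.66 ± 0.56, adjusted p = 0.0506) and that of Sag, the rod arrestin gene, at 19.5 ± 10.3 and 45.8 ± 0.5 (1.28 ± 0.56, adjusted p = 0.12).

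**Figure D3:**
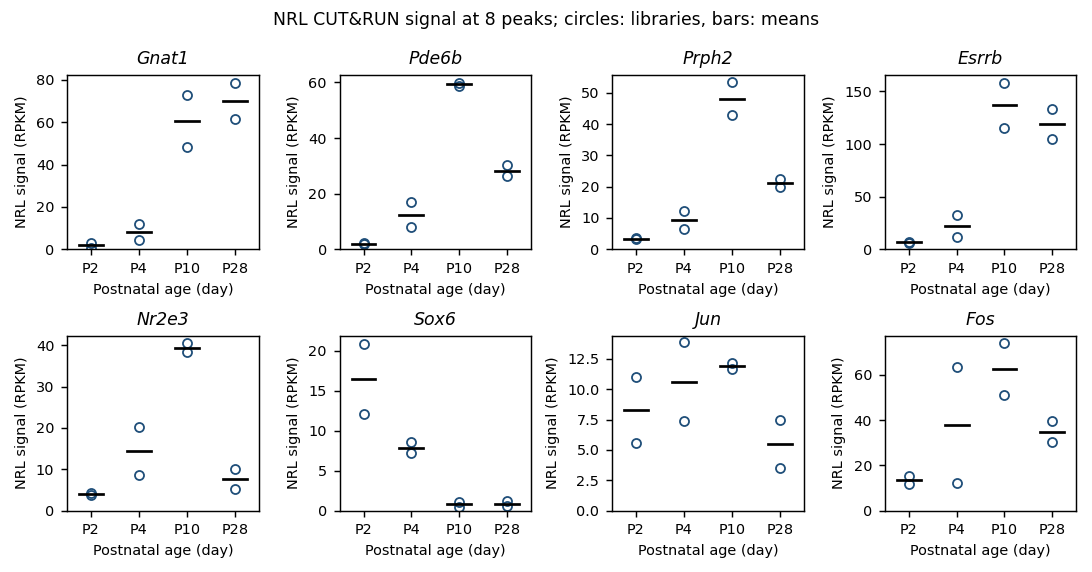
NRL signal in RPKM at 8 peaks against postnatal age; circles are libraries, 2 per age, and bars are means. Gnat1 and Esrrb stay high at P28 (70.1 and 119 RPKM), Nr2e3 has its highest mean at P10 (39.4 RPKM), Sox6 has its highest at P2 (16.4 RPKM), and Jun lies between 5.47 and 11.9 RPKM in its means.

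Photoreceptor transcription factors had 3 of 15 genes that rose (adjusted p = 0.22; 3 adjusted over the list alone). Esrrb, the orphan receptor gene needed for rod survival, rose in an intron (chromosome 12, 86507673 to 86508054) from 6.45 ± 0.73 to 119 ± 19.7 RPKM (4.00 ± 0.56, adjusted p = 0.00011). Ahr, the aryl hydrocarbon receptor gene, had 3 reads at P2 and 23 at P28 (8.05-fold higher, 2.43 to 41.9; adjusted p = 0.055 without P2 replicate 3). Mef2d changed by 1.76 ± 0.58 (adjusted p = 0.046, and 0.093 after centring). The peak at the Nrl promoter itself (chromosome 14, 55524898 to 55525124) had 16.1 and 0 RPKM in the P2 libraries and 5.99 ± 1.72 at P28 (0.74 ± 0.83, adjusted p = 0.55; −1.31 without P2 replicate 4). Nr2e3 (0.71 ± 0.56, adjusted p = 0.38) and Crx (1.37 ± 0.56, adjusted p = 0.098) did not pass.

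Genes of metabolism, synapse and cilium had smaller numbers. In glycolysis and energy metabolism 4 of 18 rose (median 1.12; adjusted p = 0.063, 0.049 after centring and 0.032 without P2 replicate 3; adjusted p = 0.83 with an estimated correlation; 7 adjusted over the list alone). They were Eno1 (3.25 ± 0.56), Gpi1, which encodes glucose phosphate isomerase (2.13 ± 0.58), the lactate dehydrogenase gene Ldha (1.74 ± 0.53) and Slc16a1, with 3 and 16 reads (5.60-fold higher, 1.60 to 30.0). In the synapse list 3 of 14 rose (adjusted p = 0.32; 4 adjusted over the list alone): Cplx4 (2.08 ± 0.59), the syntaxin gene Stx3 with 1 and 11 reads (11.6-fold, 1.68 to 497) and Egflam, which encodes pikachurin of the ribbon synapse, with 3 and 15 reads (5.25-fold, 1.49 to 28.3). Arl3, a small GTPase gene of lipidated protein transport to the cilium, was the 1 of 21 cilium genes that rose (2.02 ± 0.54; list adjusted p = 0.37; 1 adjusted over the list alone).

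Lists of other cells and functions showed single members. The RNA-binding protein gene Zfp36l1 rose (1.35 ± 0.45) among 8 progenitor genes, of which 1 rose adjusted over the list alone. The progenitor list itself leaned down, with a median of 0.21 against 0.62 for all genes (camera adjusted p = 0.17). Lrit3 rose among 4 bipolar genes with 2 and 14 reads (7.35-fold higher, 1.69 to 66.7), Kmt2a, a histone methyltransferase gene, among 18 chromatin genes with 2 and 41 reads (21.5-fold, 5.59 to 184), the mitotic checkpoint gene Bub1 among 20 cell cycle genes with 3 and 14 reads (4.90-fold, 1.37 to 26.6), and Cebpg among 18 bZIP genes (1.85 ± 0.55). Camera gave their lists adjusted p of 0.58, 0.58, 0.69 and 0.32, and the bipolar and bZIP lists leaned down. Adjusted over the list alone, Lrit3 and Kmt2a passed, Nyx fell, and no cell cycle or bZIP gene passed. No cone, ribosomal or amacrine, horizontal and ganglion cell gene passed; list medians were 0.17, 0.66 and 0.27, with adjusted p = 0.58 for each. Mitf, of the pigment epithelium, had 4.90 ± 2.48 and 1.02 ± 1.45 RPKM (−1.69 ± 0.59, adjusted p = 0.061).

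Jun, the gene of the c-Jun named in the title, had a promoter peak (chromosome 4, 95051944 to 95052735) that was in the lists of all 4 ages, with 8.25 ± 3.85 RPKM at P2, 10.6 ± 4.6 at P4, 11.9 ± 0.3 at P10 and 5.47 ± 2.77 at P28 (P28 against P2 −0.52 ± 0.56, adjusted p = 0.53). Fos, its AP-1 partner, had a peak at −18301 bp from its TSS with 13.5 ± 2.5 RPKM at P2, 37.8 ± 36.2 at P4, 62.5 ± 16.3 at P10 and 34.9 ± 6.7 at P28 (1.31 ± 0.62, adjusted p = 0.15). Atf3, Bach2, Creb1 and Jund also had peaks in the P2 list. Of the loci fixed in advance, Mef2c, Opn1sw and Ccnd1 had no peak within 50 kb.

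Outside the lists, peaks that rose from P2 to P28 included Stk35, a kinase gene, with 2 and 88 reads (46.2-fold higher, 12.4 to 388), the methyl-CpG-binding factor gene Zbtb38 (3.93 ± 0.57), Calcoco1 (3.91 ± 0.57), Dpf3, a subunit gene of the BAF remodelling complex (3.89 ± 0.57, from 2.10 to 44.8 RPKM), and St8sia1, the GD3 ganglioside synthase gene, with 0 and 17 reads (at least 5.95-fold higher, from a floor of 3 reads over the P2 libraries). Peaks that fell included Stra6, which encodes the retinol-binding protein receptor, with 54 and 1 reads (51.4-fold lower, 8.84 to 2068), Zdhhc25, of a palmitoyltransferase family (40.9-fold, 6.97 to 1654), Slc6a17 (40.0-fold, 6.80 to 1617), Glt1d1 (38.1-fold, 6.45 to 1541), Lpcat2, an acyltransferase gene (37.1-fold, 6.28 to 1504), and Sox6 (20.6-fold, 6.75 to 103). Islr fell by 3.55 ± 0.56 and Rhobtb1, an atypical small GTPase gene, by 3.49 ± 0.60 on the log2 scale. These peaks are named by the nearest TSS. Those of Stra6, Glt1d1 and Zdhhc25 lay −10334, 46649 and −34014 bp from it, the first in an intron annotated to another gene.

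Limma called 1137 peaks, 867 higher and 270 lower at P28 (76.3% higher). The median peak was 0.57 higher, and after centring 294 were higher and 653 lower (31.0% higher), with 564 calls shared in direction. After centring, Lrit3, Zfp36l1, Bub1, Cebpg, Egflam, Cplx4, Ldha and Slc16a1 no longer passed, and every named rod peak that had passed did. Genes lower at P28 that passed the test over all peaks only after centring included Notch1 (adjusted p = 0.014), Id3 (0.0099), Nyx (0.0082), Bach2 (0.020) and Mitf (0.018). By list, 3 progenitor, 2 bZIP, 1 bipolar, 1 transcription factor and 1 chromatin gene then fell. The count was 604 without P2 replicate 4, 627 without P28 replicate 3 and 707 without P28 replicate 4. Of 36 named peaks that passed, 21 did so in each fit that left out 1 library; the exceptions included Zfp36l1 (adjusted p = 0.22), Bub1 (0.30), Cebpg (0.28), Lrit3 (0.10), Gpi1 (0.14), Arl3 (0.084) and Egflam (0.071) without P2 replicate 4, and Stx3 (0.11), Cplx4 (0.12), Ldha (0.17), Slc16a1 (0.21) and Mef2d (0.12) without P2 replicate 3.

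Called peaks differed in position as well as in gene. Of all 8996 peaks, 56.8% lay within 1 kb of a TSS. Of the peaks higher at P28 than at P2, 400 (46.1%) did, against 20 (7.41%) of the lower ones (Fisher's exact test, two-sided, odds ratio 10.7, adjusted p = 2.1e-35); after centring the shares were 28.9 and 15.5% (odds ratio 2.22, adjusted p = 3.8e-06). Between P10 and P28 they were 35.3% of higher and 24.6% of lower peaks (odds ratio 1.68, adjusted p = 0.015), and 62.1 and 19.5% after centring (odds ratio 6.75). Between P4 and P10 they were 28.0 and 7.35% (odds ratio 4.91), and 17.8 and 10.2% after centring (odds ratio 1.89). Within libraries, promoter peaks took 66.3 and 59.1% of reads in peaks at P2, 62.1 and 58.3% at P4, 56.5 and 57.1% at P10, and 69.2 and 66.2% at P28. Across all ages 4128 peaks changed (limma). Of these, 3207 (77.7%) had their highest mean at P10, 10.8% at P28, 8.82% at P4 and 2.74% at P2. Of the 8996 peaks, 7489 overlapped the P10 list and 1217 the P2 list, so a highest mean at P10 is partly built into the table. Of the changed peaks with the highest mean at P28, 58.8% were promoter peaks, against 35.1% at P10. The 4128 became 1862 after centring, 1985 without P10 replicate 1 and 2197 without P10 replicate 4. With libraries scaled to their reads in peaks 1194 changed, with 28.6% highest at P2, 22.2% at P4, 28.8% at P10 and 20.4% at P28, and promoter peaks were 34.6% of those highest at P28 and 18.6% of those highest at P10.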

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

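The alternatives given here were fixed before the data were examined, except the values as deposited and limma-voom, which were chosen after seeing the data. Of 88 pairs of a named peak and a comparison, 52 passed the threshold; 24 of these did so under each of up to 20 alternatives, 30 in each fit without 1 library, and 0 turned direction. Of 1749 alternative values for named peaks, 1514 kept direction and side of the threshold, 163 lost the call, 62 gained one and 10 turned direction, all 10 at peaks that were not called: Trpm1 (−0.13 after centring, −0.20 and 1.10 without P2 replicates 3 and 4), Bhlhe23 (−0.42 after centring, −0.32 scaled to reads in peaks, −0.29 as deposited, 1.02 and −0.70 without P28 replicates 3 and 4), Prox1 (−0.31 after centring, −0.0253 scaled to reads in peaks), Slc6a9 (0.034 and −0.94 without P2 replicates 3 and 4) and Nrl (2.78 and −1.31 without P2 replicates 3 and 4). Some alternatives leave the log2 change of a peak as it is, so they could not turn a direction. For P28 against P2 these were limma without trend, only the 2 ages compared, the replicate block and stricter thresholds. Leaving out a P4 or P10 library did not move that change either. The 2-fold threshold ended no call in any comparison. The counts of kept values therefore overstate how far the direction was tested. A fit without 1 library leaves a lone sample at that age, which is assumed to vary like the other groups. The causes were not tested unless stated.

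Counts of changed peaks depended on the scaling and the pseudocount. For P4 against P2, where limma called 0 peaks and 1365 had an unadjusted p under 0.05, the count was 41 without the weakest 1 in 4 peaks, 8 with a pseudocount of 0.1, 95 with 4, 19 with only the 2 ages and 8 with limma-voom. For P10 against P4 (1541) it was 552 after centring, 217 scaled to reads in peaks (91 higher, 126 lower), 8 and 2751 with pseudocounts of 0.1 and 4, 489 at an adjusted p under 0.01 and 560 as deposited. For P28 against P10 (1974) it was 1155, 294 (69 higher, 225 lower), 474 and 3030, 753 and 886 in the same order, and 3246 with only the 2 ages. For P28 against P2 (1137) it was 336 with a pseudocount of 0.1, 388 at 0.01 and 404 as deposited. For any age (4128) it was 1862 after centring, 1194 scaled to reads in peaks, 1520 with a pseudocount of 0.1, 2119 at 0.01 and 2179 as deposited. Of the calls on deposited values, 454, 778 and 330 in the last 3 comparisons and 1918 at any age were also calls on rebuilt values.

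Without 1 library the counts ran from 0 to 836 for P4 against P2 (836 without P4 replicate 3), 215 to 3040 for P10 against P4 (without P4 replicates 3 and 4), 507 to 2691 for P28 against P10 (without P10 replicate 1 and P4 replicate 3), 604 to 1650 for P28 against P2 (without P2 replicate 4 and P4 replicate 3) and 1985 to 4814 at any age (without P10 replicate 1 and P4 replicate 4).

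Of gene lists, 1 passed for P28 against P2 and 4 over the consecutive steps. With an estimated correlation 0 and 0 passed. For P28 against P2, 3 passed with peaks within 10 kb and 2 after centring; over the steps 2 passed with the mean over all peaks of a gene, and those lost were the rod and transcription factor lists at P4 against P2. Without 1 library 1 to 2 lists passed for P28 against P2 and 2 to 5 over the steps.

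With the replicate number as a block, 69 peaks changed for P4 against P2, 183 for P10 against P4, 432 for P28 against P10, 1110 for P28 against P2 and 2095 at any age. The deviations of same-numbered libraries correlated at 0.085 (P2 and P4), 0.050 (P2 and P28) and 0.029 (P4 and P28), all under 0.1. P10 was not in this check. Low correlations do not exclude a shared litter or day, so whether the numbers pair the samples stays open.

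The share of P2 peaks found in the P4 list was 86.7% with the stricter 50% of each list, 71.0% at 50% reciprocal overlap and 57.9% with lists of equal length. For P2 in P10 the last 2 were 71.5 and 42.3%, for P2 in P28 they were 51.2 and 41.4%, for P4 in P10 the 3 were 87.8, 70.3 and 63.0%, and for P28 in P10 the last 2 were 64.5 and 55.7%. With a 3 kb window the promoter shares were 66.3, 66.5, 64.2 and 78.5% in order of age, and at equal length 54.3% at P4, 46.3% at P10 and 69.3% at P28. Within 1 kb, the stricter 50% of each list gave 57.5, 58.2, 55.7 and 72.9% in order of age.

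Medians were 4 to 15 reads per peak. In simulated data with equal expected reads in peaks per library, a 2-fold change was recovered in 0% of peaks, in the stronger 50% of them as in all. A 4-fold change was recovered in 38.8% of all and 55.2% of the stronger 50%. Limma-voom on the recovered reads called 2073 peaks for P10 against P4, 2060 for P28 against P10, 1034 for P28 against P2 and 4660 at any age. The other count-based alternatives were planned for values in counts and were not run, nor were the motif results.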

Other observations

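Some genes carried many NRL peaks. The gene with the most was Ankrd33b, an ankyrin repeat gene, with 8 peaks, followed by Epb41, a cytoskeletal protein gene, with 7. Casz1, Cerkl, Dpf3, Esrrb, Pitpnm3, Arhgap26, Bicdl1, Nadk2, Pcbp3 and Tnrc6b had 6 each. Pde6a and Ldha had 5 each, and Abca4 and Arl3 had 4. Peaks in the lists of all 4 ages were 666 of the P2 peaks, of which 77.8% lay within 1 kb of a TSS, against 21.0% of the 105 peaks found at P2 alone.

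The tests given in the next paragraphs were chosen only after the results they bear on were seen.

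The first pattern is the maximum at P10, where 91.2% of called peaks were higher than at P4 and 5.88% of those called at P28 against P10 were higher at P28. With libraries scaled to reads in peaks 41.9% of P10 against P4 calls were higher, but that scaling itself pulls calls towards balance, so a difference in the share of reads inside peaks cannot be told apart from age as the source of the one-sided count. That scaling divides each library by 1 factor, so for the rod genes it bears only on a difference that moves all peaks alike. Such a uniform difference is argued against as the whole cause of the rod rise, since the rod list median was still 1.25 higher (log2) at P10. The gap was 1.09 between the closest libraries, with at most 0.31 between replicates. A difference that lifts some peaks more than others is not removed by 1 factor and cannot be told apart from age. The rod genes were also read at their strongest peaks, and 30 had a peak in the P10 list against 16 in the P4 list. In the 667 peaks that overlapped the lists of all 4 ages, the level fell by 1.08 (log2 median) to P28 on the deposited library scales, with 0.94 between the closest libraries. The share of reads in peaks was 3.08 and 2.84% at P10 and 1.52 and 1.51% at P28. The fall in the 667 peaks was not computed with libraries scaled to that share. A difference in the share therefore cannot be told apart from age as its source. For these peaks the fall argues only against a table drawn mostly from P10 peaks as the whole cause. For the other peaks, and for the rise from P4 (0.79, with P4 replicates 0.98 apart), such a table cannot be told apart from age. Age itself stays open and untested, as do other differences between the P10 libraries and the rest.

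The second pattern is the larger promoter share at P28. Weaker enrichment that adds open promoters, as the whole cause, would give the P2 list, from the libraries with the lowest share of reads in peaks, at least the share of P28. At equal length the P2 share was lower (a difference of −7.29 points). The share of reads in peaks was counted over 8996 peaks, of which 7489 overlapped the P10 list and 1217 the P2 list. A low share of reads at P2 is thus partly built in and is no separate measure of enrichment. The difference of P2 from P28 therefore does not decide the question. From P2 to P10, however, the share at equal length fell (62.0, 54.3 and 46.3%) while the share of reads in peaks rose. For the difference of P28 from P10, weaker enrichment therefore cannot be told apart from age. The gap between promoter and other peaks within a library was 0.77 larger (log2) at P28 than at P10, with 0.71 between the closest libraries and at most 0.11 between replicates. A library scale hardly moves such a gap, so it does not test the scales. The peaks also come from these same lists, so the gap is no separate support for the pattern. A change of binding with age remains a hypothesis that these data did not test, and open chromatin at promoters specific to mature retina was not measured here.

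The third pattern is P4 replicate 4, which lies closer to P10 than P4 replicate 3 does. A P10 sample under a P4 label is argued against, because its highest correlation with a P10 library was 0.68 against 0.74 with its own replicate, and its rod list median stood 0.83 above that of all peaks, against 1.94 in the lower P10 library and 0.33 in P4 replicate 3. A higher share of reads inside peaks cannot be told apart from age. The correlation of P4 replicate 4 exceeded that of P4 replicate 3 by at least 0.19 with the P10 libraries and by −0.012 and 0.030 with the P2 libraries. P4 replicate 3 already correlated at 0.64 and 0.61 with the P2 libraries, above the 0.60 between these, which left little room for a gain there. Retinas slightly further along in development than those of P4 replicate 3 may be a candidate explanation that stays open.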
